A study of Mus musculus with 9 samples.

How the data were processed

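RNA of γδ T cells from C57BL/6 mice was hybridised to Affymetrix Mouse Gene 2.0 ST arrays, 3 arrays for each of 3 subsets. Per the labels' protocols, IELs were released from pieces of intestine by agitation at 37 °C in a buffer with a reducing agent and EDTA and collected on a Percoll gradient, while lymph nodes were mashed and filtered. The gates that define the subsets are not given in the sources used here beyond the list of antibodies. Groups were taken from the sample titles.

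The deposited table holds log2 values for 41345 array rows on 9 arrays. The authors used oligo and RMA, per the submitters' processing notes, which normalizes arrays to each other and summarizes probes per transcript; versions, filters and whether other arrays were normalized together are not given in the sources used here. The values run from 0.785 to 13.5 with no missing value, and array medians from 4.25 to 4.43. The table carries no detection calls, so a low value has no stated background, and RMA compresses differences of dim genes. No column of another sample was used.

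Rows were named through the platform's annotation: 23521 rows had 1 gene symbol, 1814 several and 16010 none. Of the rows with 1 symbol 23328 were found by Entrez identifier in the RefSeq gene table of GRCm38.p6, and no symbol changed. Only rows with 1 symbol were tested, as 22180 genes, each by its row of highest mean. Of these, 1082 had more than 1 row. Called genes with several rows numbered 56, 1 and 52 for IELs against Naive-like, Type-1 against Naive-like and IELs against Type-1 cells. Some row had the opposite sign in 12, 0 and 14 of these genes. In a fit of all rows, every row of the gene passed in the same direction in 3, 0 and 0 of them. Coordinates are not printed, since the files name no genome build. List genes without a row of 1 symbol are not analysed here, and of the γδ T-cell receptor chains 2 genes had such a row, Trgv5 and Trgv6, so that list was not tested as a set.

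Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per subset over all 9 arrays, contrasts, eBayes without trend), two-sided, with Benjamini-Hochberg adjustment over 22180 genes and a threshold of 0.05. The fit had 6 residual and 6 prior degrees of freedom. All 3 pairwise comparisons and an F test over the subsets came from this fit. A gene was exclusive to a subset if it was higher there than in each other subset, and shared by a pair if each of the pair was higher than the remaining subset. Since these comparisons share arrays, overlaps and the correlation of differences were set beside 50 simulations of unchanged groups with the genes' own spread.

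There were 28 gene lists, fixed before the data were examined, of which 27 had at least 3 measured genes. They were tested with limma's camera at a preset correlation of 0.01, adjusted over 81 tests, again with an estimated correlation, and with fry, which asks whether a list moves one way on balance without comparing it with other genes. At the preset correlation 20, 13 and 18 lists shifted in IELs against Naive-like, Type-1 against Naive-like and IELs against Type-1 cells, and 9, 4 and 6 of these calls held with an estimated correlation. The genes named in the text follow a rule fixed at the same time: per comparison and direction the 12 largest differences among genes that passed the test, with no overlap between arrays and with the higher mean above the median of all genes (4.52), leaving out predicted, non-coding and receptor segment genes; 8 genes per marker class; up to 4 members per list that passed, or 2 where none did; and all antibody targets. Genes named outside it are marked.

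Tested on simulated data with 22180 genes, 200 of them changed, the fit recovered 43.3%, 97.0% and 100% of log2 changes of 1, 2 and 3 for IELs against Naive-like cells, 46.3%, 94.0% and 100% for Type-1 against Naive-like cells and 40.3%, 95.5% and 100% for IELs against Type-1 cells, with 6, 10 and 13 false calls. The list of 59 ribosomal protein genes, shifted by 0.5, was the 1 list called of 27. The genes were simulated independently, whereas the estimated correlation within the real lists reached 0.439 (oxidative phosphorylation). The simulation therefore cannot show how often camera at the preset correlation calls real lists falsely.

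Alternatives fixed beforehand were a filter on dim genes at the 40th percentile, array medians subtracted, quantile normalization again, cyclic loess, a trend with robust spread, array weights, the mean of a gene's rows, all rows, a minimum log2 difference of 1, only the subsets compared, the replicate number, description set or date code as a block, the arrays without the date code, each array left out, an estimated correlation, and genes of 1 list only. Removing IEL replicate 1 and Type-1 replicate 3, the arrays of lowest weight, was added after seeing the data. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots with matplotlib 3.10.9.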

Results

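Gene expression was measured in γδ T cells of C57BL/6 mice, a lineage of T cells whose receptor is built from γ and δ chains. The samples form 3 subsets of 3 arrays each, 9 arrays in all. Intraepithelial lymphocytes (IELs) came from the epithelium of the small intestine, while Naive-like and Type-1 cells came from peripheral lymph nodes. Subset and tissue therefore differ together in every comparison with IELs, and only Type-1 against Naive-like cells lies within one tissue. The labels call the 3 arrays of a subset biological replicates without saying whether each is 1 mouse or a pool, so p-values measure the spread between these samples. Arrays of the same subset correlated at 0.947 to 0.982 over the 22180 genes tested, and arrays of different subsets at 0.912 to 0.975. The number of arrays limits the precision, and the median standard error of a difference was 0.24 on the log2 scale. All values are log2, differences carry their standard error, and n = 3 arrays per subset throughout.

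**Figure D1:**
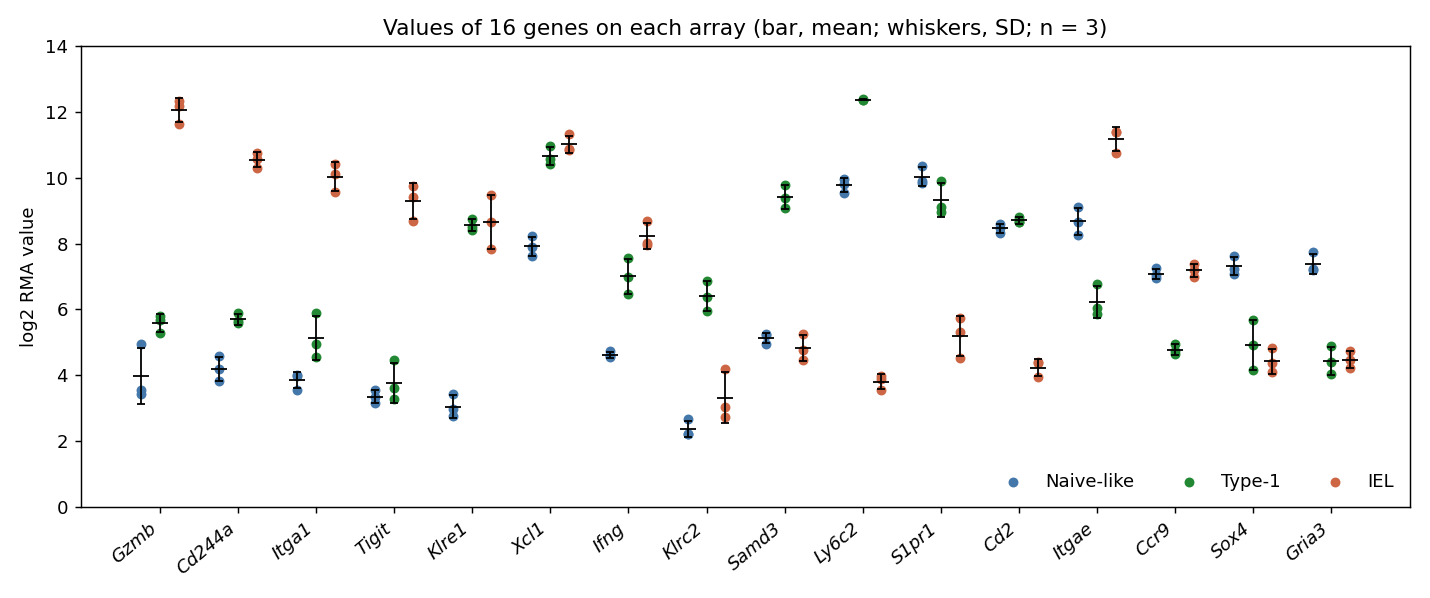
Log2 expression values (vertical axis) of 16 genes (horizontal axis) on each of the 9 arrays, coloured by subset, with the mean as a bar and the SD as whiskers. Gzmb averages 12.05 in IELs against 3.98 in Naive-like cells, and Klre1 is high in both IELs (8.65) and Type-1 cells (8.56).

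The comparison of IELs with Naive-like cells asked how the intestinal subset differs from the lymph node subset with naive features. Gzmb, which encodes the cytotoxic protease granzyme B, was higher in IELs by 8.06 ± 0.36, with a mean of 12.05 ± 0.37 (SD, n = 3) against 3.98 ± 0.85. Cd244a, an activating and inhibitory receptor of the SLAM family, was higher by 6.35 ± 0.23, the collagen-binding integrin gene Itga1 by 6.18 ± 0.33, the inhibitory receptor gene Tigit by 5.93 ± 0.32 and the chemokine gene Ccl3 by 5.73 ± 0.36. In the other direction Ly6c2, a surface protein of lymphoid and myeloid cells, fell by 5.97 ± 0.20, and S1pr1, the receptor that guides lymphocytes out of lymph nodes, fell by 4.83 ± 0.33. The adhesion molecule gene Cd2 (-4.23 ± 0.20) and Cd5, a negative regulator of antigen receptor signalling (-3.81 ± 0.25), fell too. The Paneth cell defensin genes Defa22, Defa21 and Defa24 stood among the 12 genes that the naming rule took as most increased, at 7.20 ± 0.29, 6.89 ± 0.25 and 5.63 ± 0.31, as did the carbonic anhydrase gene Car2 at 6.01 ± 0.19.

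By function, 15 of 20 measured genes for cytotoxic granules and death ligands rose in IELs and none fell, with 16 rising when adjusted over the list alone. Among them Gzma rose by 5.63 ± 0.34, Fasl by 4.94 ± 0.26 and Gzmk by 4.58 ± 0.25. Of 26 genes for natural killer (NK) receptors and their adaptors, 13 rose and 1 fell (18 and 1 adjusted over the list alone), led after Cd244a by the signalling adaptors Fcer1g (5.60 ± 0.32) and Tyrobp (5.28 ± 0.33) and the receptor Klre1 (5.60 ± 0.34). Of 13 markers of NK cells and innate lymphoid cells, 7 of which stand in other lists too, 8 rose and 1 fell in the same contrast (8 and 1 adjusted over the list alone; median 1.78; camera adjusted p = 1.7e-07, and 0.032 with an estimated correlation). Of 34 genes for tissue residency and gut homing, 21 rose and 1 fell (25 and 2 adjusted over the list alone). Of these 34 genes 22 stand in other lists too. Rgs1 and Nr4a2 rose by 5.14 ± 0.47 and 4.18 ± 0.44, and Itgae, the integrin chain that binds E-cadherin on epithelial cells, by 2.51 ± 0.30. The list for naive cells and lymph node homing went the other way, with 19 of 27 members lower and 1 higher (24 and 2 adjusted over the list alone). Dapl1 (-4.19 ± 0.34), the interleukin 6 receptor gene Il6ra (-3.95 ± 0.23) and the transcription factor gene Lef1 (-3.50 ± 0.25) were among those that fell. For the cytotoxic, NK receptor, residency and naive lists the limma camera test gave adjusted p of 8.7e-23, 4.1e-20, 5.5e-25 and 2.2e-30, and 0.012, 0.0069, 0.014 and 0.037 with an estimated correlation.

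Among inhibitory and regulatory molecules 14 of 30 rose and 2 fell (16 and 4 adjusted over the list alone). Cd200r2, Lilrb4a and Cd200r1 rose by 6.46 ± 0.57, 5.28 ± 0.61 and 5.22 ± 0.29; the camera call for this list was lost with an estimated correlation, at adjusted p = 0.068. Of 21 genes of the type 1 and interferon-γ programme, 10 rose and 3 fell (14 and 4 adjusted over the list alone), with Ifng up by 3.60 ± 0.28 and Il12rb2 by 3.41 ± 0.35, while the transcription factor gene Eomes (-1.89 ± 0.27) and the receptor gene Il18r1 (-3.15 ± 0.31) fell. This list had an adjusted p = 0.059 with an estimated correlation. All 30 interferon-stimulated genes were lower in IELs and 11 passed the test, 19 adjusted over the list alone, among them Oasl2 (-2.94 ± 0.22), Usp18 (-2.92 ± 0.20) and Ifit1 (-2.45 ± 0.25). All 19 sterol synthesis genes were higher and 9 passed, 16 adjusted over the list alone, with Cyp51 at 2.96 ± 0.27 and Sqle at 2.65 ± 0.45. These last lists had an adjusted p = 0.032 and 0.037 with an estimated correlation. In the same arrays all 32 epithelial genes were higher and 24 passed.

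Genes typical of another cell type and of stress moved with the same contrast. Of 32 genes typical of intestinal epithelium 24 rose in IELs and none fell (26 adjusted over the list alone; median 1.75; camera adjusted p = 2.7e-33, and 0.032 with an estimated correlation). Fabp2, Dmbt1 and Cdh1 rose by 3.94 ± 0.36, 3.83 ± 0.49 and 3.71 ± 0.37. Of 17 heat shock genes 11 rose and none fell (14 adjusted over the list alone), including Hspa1a at 3.51 ± 0.48 and Dnajb1 at 1.99 ± 0.24, and the camera call held at adjusted p = 0.032 with an estimated correlation. Of 35 immediate early genes 14 rose and 1 fell (18 and 2 adjusted over the list alone), Tnfaip3 by 3.09 ± 0.44 among them, with an adjusted p = 0.19 with an estimated correlation. Rgs1 and Nr4a2 belong both to this list and to that for tissue residency.

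The limma test called 1152 of 22180 genes at an adjusted p under 0.05 (5.19%), 792 higher and 360 lower in IELs. Of these, 688 and 303 differed at least 2-fold, and 3150 genes had an unadjusted p under 0.05. In 20.1% of all genes the 3 IEL arrays lay wholly above or below the 3 Naive-like arrays, where chance gives 10%. The descriptions of replicate 3 of every subset carry a date code, which the other arrays lack. With that code as a term the count was 1312, and within the 6 arrays without it 534 genes passed, of which 530 differed in the same direction between the date-coded arrays. Array weights raised the count to 1920.

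The comparison of Type-1 with Naive-like cells asked how these lymph node subsets differ. Klre1, a lectin-like NK receptor gene, was higher in Type-1 cells by 5.51 ± 0.34, with a mean of 8.56 ± 0.17 (SD, n = 3) against 3.05 ± 0.34. Samd3 was higher by 4.28 ± 0.25, Ctla2a by 4.04 ± 0.29, and the receptor genes Klrc2, Klrc3 and Klrk1, the last of which encodes NKG2D, by 4.03 ± 0.35, 3.99 ± 0.41 and 3.89 ± 0.33. The glutamate receptor subunit gene Gria3 fell by 2.95 ± 0.26, and Itgae (-2.44 ± 0.30), the transcription factor gene Sox4 (-2.40 ± 0.34) and Ccr9, a chemokine receptor that directs lymphocytes to the small intestine (-2.30 ± 0.19), fell too. Dntt, which encodes the DNA polymerase that adds nucleotides to rearranging receptor genes, fell by 2.18 ± 0.37. Sox4 has 2 rows on the array, which did not both pass when all rows were tested.

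Of 21 genes of the type 1 and interferon-γ programme 9 rose and none fell (14 adjusted over the list alone). Xcl1 rose by 2.73 ± 0.23, Il18rap, a chain of the interleukin 18 receptor, by 2.60 ± 0.33, Ccl5 by 2.43 ± 0.19 and Ifng by 2.38 ± 0.28, and Tbx21, which encodes the transcription factor T-bet, by 1.95 ± 0.29. Of 26 NK receptor and adaptor genes 11 rose and none fell (14 adjusted over the list alone), and 3 of 20 cytotoxic granule and death ligand genes rose, namely Slamf7 (2.67 ± 0.22), Gzmm (2.56 ± 0.22) and Fasl (2.46 ± 0.26), or 8 adjusted over the list alone. Gzmb and Gzma did not pass the test, at 1.60 ± 0.36 and 0.41 ± 0.34. With an estimated correlation these 3 lists kept their camera calls at adjusted p = 0.014, 0.0048 and 0.032. Interferon-stimulated genes were lower in Type-1 cells too, 25 of 30 by sign with a median of -0.30, though only Igtp passed (-1.28 ± 0.22), or 2 adjusted over the list alone. Camera gave this list an adjusted p of 4.1e-08, and 0.098 with an estimated correlation. The naive and lymph node homing list had 2 of 27 members lower, Sox4 and Il6ra (-1.59 ± 0.23), and 7 lower and 3 higher adjusted over the list alone; its adjusted p was 3.2e-06, and 0.29 with an estimated correlation. None of the 32 epithelial, 17 heat shock or 35 immediate early genes passed the test, with medians of 0.10, 0.12 and -0.16; camera placed the immediate early list lower at adjusted p = 0.029, but adjusted p = 0.64 with an estimated correlation, and the call was lost without Naive-like replicate 2 (adjusted p = 0.75) or Type-1 replicate 2 (median 0.02, adjusted p = 0.92). Of 13 markers of NK cells and innate lymphoid cells, 4 rose, including Ncr1 (2.24 ± 0.39) and Klrb1c, which encodes NK1.1 (2.50 ± 0.32); 7 of these 13 markers stand in other lists too, and the list had an adjusted p = 0.014 with an estimated correlation.

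The limma test called 63 genes (0.284%), 47 higher and 16 lower in Type-1 cells, each at least 2-fold, and 1437 genes had an unadjusted p under 0.05. The groups did not overlap in 11.4% of genes, against 10% by chance. With the date code as a term 76 genes passed, and within the 6 arrays without it 20, all of which differed in the same direction between the date-coded arrays. The count and its balance rested on single arrays: 34 genes passed without Naive-like replicate 3, and without Type-1 replicate 3 there were 87, of which 41 were higher and 46 lower. It was 35 over all array rows, and 110 (46 higher, 64 lower) without IEL replicate 1 and Type-1 replicate 3, the arrays of lowest weight, an alternative chosen after seeing the data.

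**Figure D2:**
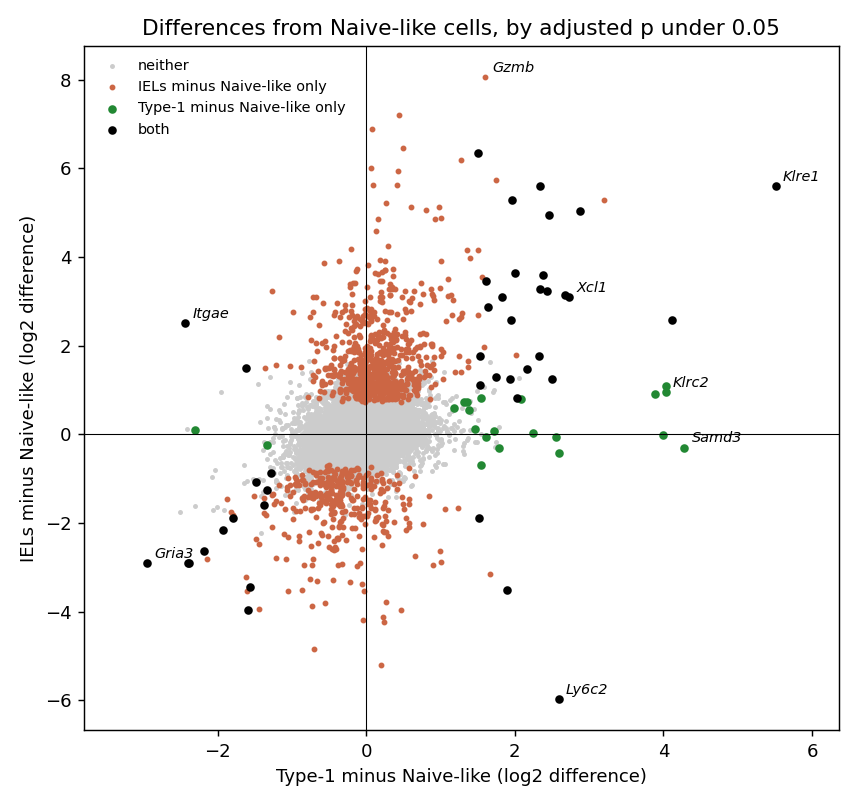
Log2 difference from Naive-like cells of every tested gene in Type-1 cells (horizontal axis) and IELs (vertical axis), coloured by which limma tests passed. Klre1 lies far out on both axes (5.51 and 5.60), Samd3 only on the horizontal one (4.28 and -0.30), and Ly6c2 rises in Type-1 cells (2.59) and falls in IELs (-5.97).

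The comparison of IELs with Type-1 cells set the intestinal subset against the lymph node subset that shares some of its effector genes. Ly6c2 was lower in IELs by a log2 difference of -8.56 ± 0.20, the largest decrease among the genes named, from 12.36 ± 0.02 (SD, n = 3) in Type-1 cells to 3.80 ± 0.23. Il18r1 and Samd3 were lower too, at -4.83 ± 0.31 and -4.58 ± 0.25, as were S1pr1 (-4.13 ± 0.33) and Klrc3 (-4.00 ± 0.41). Gzmb was higher in IELs by 6.46 ± 0.36, Tigit by 5.51 ± 0.32, Gzma by 5.22 ± 0.34 and Itgae by 4.95 ± 0.30. Defa21 and Defa22, at 6.81 ± 0.25 and 6.76 ± 0.29, had the largest increases among the genes named.

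Of 34 residency and gut homing genes 22 rose and 1 fell (23 and 2 adjusted over the list alone), and of 20 cytotoxic genes 10 rose and 1, Gzmm, fell by 2.62 ± 0.22 (12 and 1 adjusted over the list alone); these lists had an adjusted p = 0.014 and 0.023 with an estimated correlation. NK receptor and adaptor genes went both ways, with 9 of 26 higher and 5 lower (12 and 6 adjusted over the list alone): Cd244a, Sh2d1b1 and Klrh1 rose by 4.84 ± 0.23, 3.51 ± 0.32 and 3.45 ± 0.29, and its adjusted p was 0.017, and 0.15 with an estimated correlation. The camera call of this list was also lost without Type-1 replicate 1 (adjusted p = 0.087) or replicate 3 (adjusted p = 0.055) and within the arrays without the date code (adjusted p = 0.13), and its median, 0.17, was -0.03 without IEL replicate 1. Markers of NK cells and innate lymphoid cells split too, with 5 of 13 higher and 3 lower, a median of -0.17 and a mean of 0.68. For these markers camera gave an adjusted p of 0.17 and fry 0.035. The type 1 and interferon-γ list had 7 of 21 members higher and 4 lower (8 and 5 adjusted over the list alone), with Ccl3 up by 3.97 ± 0.36 and Eomes down at -3.41 ± 0.27. For this list the median was 0.30, the mean -0.26, and camera and fry pointed opposite ways, at adjusted p of 0.67 and 0.0094. By sign 12 of its members were higher and 9 lower, and Ly6c2, at -8.56, had by far the largest difference. Of 27 naive and homing genes 15 fell and none rose (21 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation), including Slamf6 (-2.84 ± 0.39) and Il7r (-2.80 ± 0.23). Of 30 inhibitory and regulatory genes 15 rose and 3 fell (17 and 3 adjusted over the list alone; adjusted p = 0.059 with an estimated correlation), among them Tgfb3 (3.75 ± 0.37). Sterol synthesis genes rose in 15 of 19 cases (16 adjusted over the list alone), with Cyp51 at 3.54 ± 0.27 and Fdps at 2.66 ± 0.40 and an adjusted p = 0.032 with an estimated correlation, and interferon-stimulated genes fell in 6 of 30 cases (7 adjusted over the list alone; adjusted p = 0.099 with an estimated correlation). Epithelial genes rose in 22 of 32 cases, heat shock genes in 9 of 17 and immediate early genes in 15 of 35, with 1 of the last lower; adjusted over the list alone 26, 13 and 19 rose. The camera adjusted p of these lists was 0.036, 0.036 and 0.14 with an estimated correlation.

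The limma test called 1140 genes (5.14%), 827 higher and 313 lower in IELs, 696 and 252 of them at least 2-fold, and 3609 had an unadjusted p under 0.05. The groups did not overlap in 19.8% of genes, against 10% by chance. With the date code as a term the count was 1374, and within the 6 arrays without it 565, of which 549 differed in the same direction between the date-coded arrays. It was 732 without IEL replicate 2 and 724 without IEL replicate 3. In the F test the number of genes differing among the 3 subsets was 1200 (5.41%). It was 1406 with the date code as a term, 1884 with array weights, 527 within the arrays without the date code, and 771 or 778 without IEL replicate 2 or 3.

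**Figure D3:**
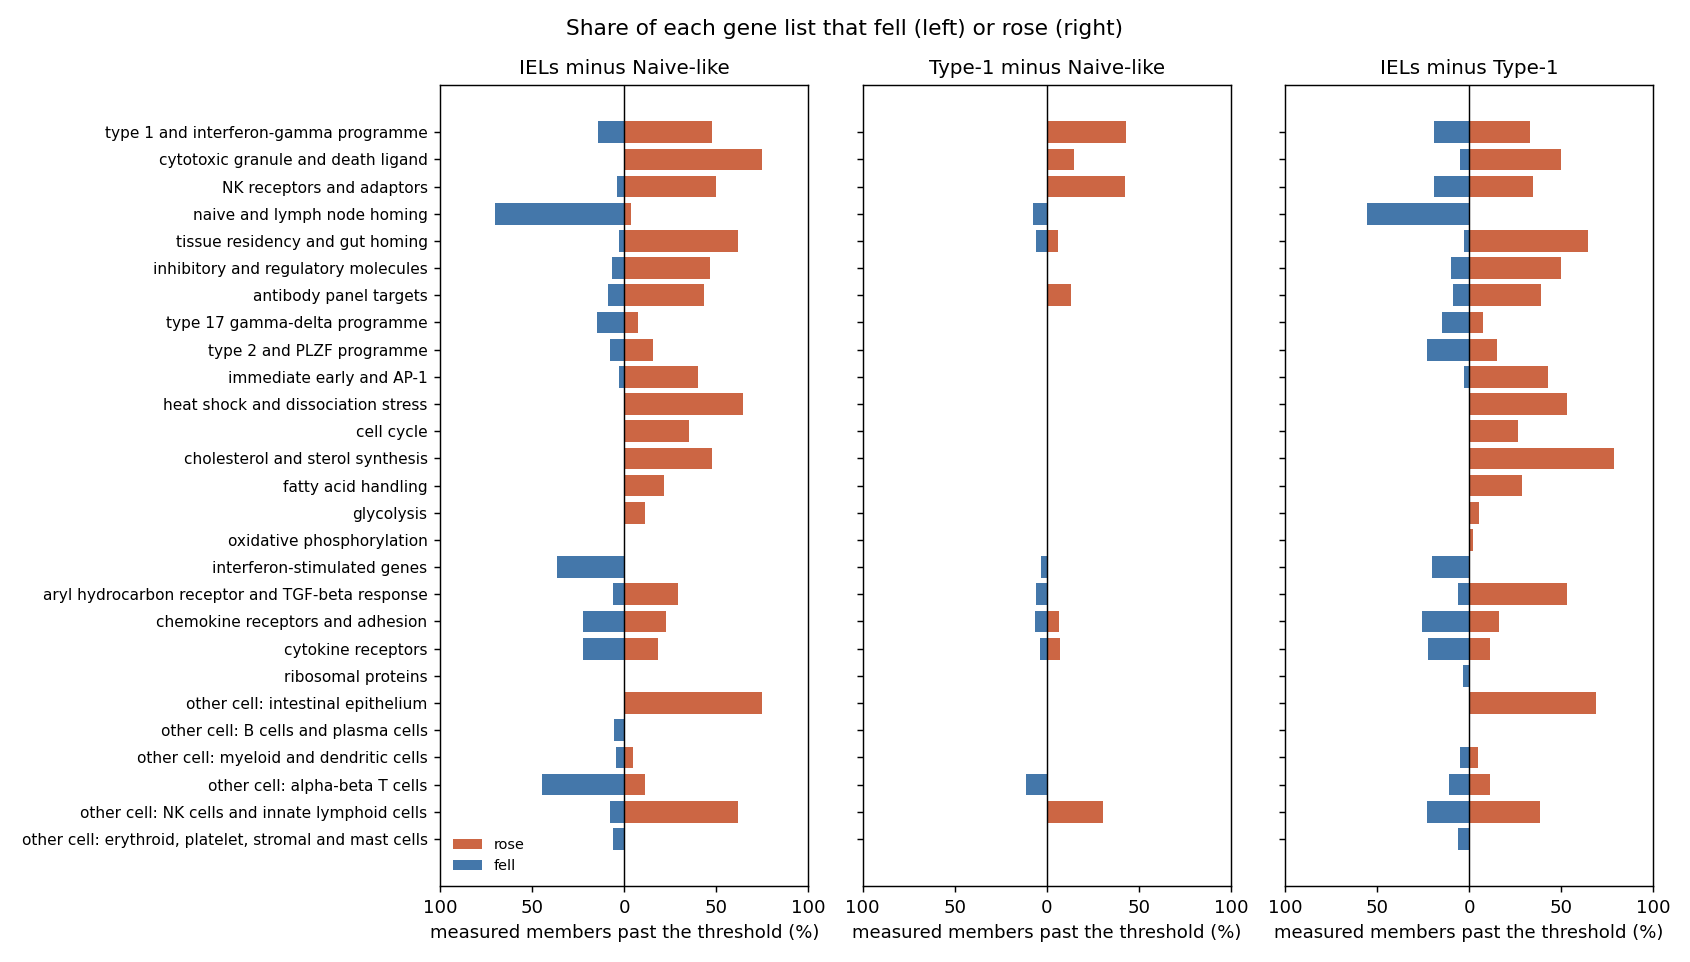
Percentage of the measured members of each of 27 gene lists that rose (right) or fell (left) past the limma threshold, 1 panel per comparison. Of the genes for cytotoxic granules and death ligands 15 of 20 rose in IELs against Naive-like cells and 3 of 20 in Type-1 cells.

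The series title names exclusive and shared markers, and genes were placed by 2 tests each. As higher in IELs than in each other subset 598 genes passed, led by Defa21, Defa22, Gzmb, Cd200r2 and Car2. Beside them, 24 of 32 epithelial list genes passed as higher in IELs than in Naive-like cells. Those exclusive to Type-1 cells numbered 20, among them Samd3, Klrc3, Klrc2, Klrk1, Ctla2a, Il18rap and Gzmm, and those exclusive to Naive-like cells 12, among them Gria3, Sox4, the receptor gene Plxdc2, Dntt, Amigo2 and Igf1r. Shared by IELs and Type-1 cells, and lower in Naive-like cells, were 25 genes, including Klre1, Klra5, Xcl1, Slamf7, Fasl, Ccl5 and Ifng. Naive-like and Type-1 cells shared 199 genes over IELs, including Ly6c2, Atp8b4, Cd2, Dapl1 and S1pr1. IELs and Naive-like cells shared 4, namely Itgae, Ccr9, Trat1 and U2af1. A gene can belong to an exclusive and a shared class, as Ly6c2 did, and 838 genes belonged to any class. Independent lists of the same sizes would overlap in 29.5, 0.66, 0.26, 1.68, 5.08 and 0.60 genes in the order given, and simulated unchanged groups gave at most 1 gene in any class. Almost no gene passes when nothing differs, so the simulated counts do not show how much overlap the shared arrays add where subsets differ, and part of the excess may come from them. The smallest classes were unstable: with 1 array left out, those exclusive to Naive-like cells ranged from 2 without Naive-like replicate 3 to 19 without Type-1 replicate 3, those shared by IELs and Type-1 cells fell to 13 without Naive-like replicate 3, and those shared by IELs and Naive-like cells reached 24 without Type-1 replicate 3. The number of markers exclusive to IELs was 397 without IEL replicate 2 and 390 without IEL replicate 3. Within the 6 arrays without the date code, where fewer arrays were fitted, every class was smaller (counts below).

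Of the 47 genes higher in Type-1 than in Naive-like cells 25 were also higher in IELs than in Naive-like cells and 3 were lower, namely Ly6c2, Ms4a4c and Eomes. Of the 16 lower genes 12 were also lower in IELs and 2, Itgae and Trat1, were higher. Across the 22180 genes, which are not independent replicates, the differences of IELs and of Type-1 cells from Naive-like cells correlated at r = 0.302 ± 0.128 (jackknife SE over arrays; Spearman's rho 0.285), where 50 simulations of unchanged groups with the same design gave 0.500. Their covariance was 0.0585 against 0.0346 simulated, a difference of 0.0239, and 59.4% of genes had the same sign against 66.6% simulated. The simulated r follows from the shared Naive-like arrays alone. Real differences in one subset, which the simulations lack, can lower r and the share of equal signs. Values of these below the simulated ones therefore do not show that the subsets move less alike than unchanged groups. The simulated arrays varied independently, whereas the date-coded arrays deviated together across subsets at correlations of 0.229 to 0.382, so the simulated values leave out that shared deviation. With 3 Naive-like arrays the shared group could not be split into parts of at least 2 arrays.

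The subsets were also compared on the genes of the proteins that the labels' antibody panel detects, 23 of which were measured. The gates are not given in the sources used here, so differences in these genes may in part restate how the subsets were defined. Of these, 10 rose and 2 fell in IELs against Naive-like cells, 3 rose in Type-1 against Naive-like cells, and 9 rose and 2 fell in IELs against Type-1 cells (12 and 2, 5 with 1 lower, and 10 and 3 adjusted over the list alone). In IELs against Naive-like cells Cd8a rose by 3.40 ± 0.44, Entpd1 and Nt5e, which encode CD39 and CD73, by 2.45 ± 0.21 and 2.70 ± 0.34, and Ctla4 by 2.65 ± 0.32, while Cd8b1 fell by 2.81 ± 0.47. Cxcr3 rose by 1.93 ± 0.18 in Type-1 cells and by 1.25 ± 0.18 in IELs. Ptprc, Cd3d, Cd3e, Cd4, Foxp3, Gata3, Ccr6, Pdcd1 and Tgfb1 passed none of the 3 tests, and Cd3d lay at 11.16, 11.10 and 11.17 in Naive-like cells, Type-1 cells and IELs and Cd3e at 10.84, 10.61 and 11.72. With an estimated correlation the panel's camera adjusted p in the IEL comparisons was 0.059 and 0.11. Of its 23 measured genes 19 stand in other lists too. Over the rest, namely Ptprc, Cd3d, Cd3e and Cd3g, camera at the preset correlation gave an adjusted p of 0.34 and 0.15. So few genes do not speak for the panel.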

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

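The tests of explanations below were chosen after the results were seen; the count of other splits was planned before they were computed. Rows without a gene symbol lie outside the genes reported above, and over all 41345 rows 71 of these 16010 rows were higher and 63 lower in IELs than in Naive-like cells, and 2 were higher and 2 lower in Type-1 than in Naive-like cells. In IELs against Type-1 cells 90 were higher and 38 lower.

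Epithelial transcripts were higher in IELs: 24 of 32 listed genes passed, and the Paneth cell gene Defa24 reached 9.05 ± 0.63 (SD, n = 3). The list was fixed before the data were examined, and 2 of its genes stand in another list. Over the 3 IEL arrays these 24 genes deviated together, with a mean pairwise correlation of 0.592, against a 95th percentile of 0.336 among 10000 random sets of other genes higher in IELs, of which 5 sets reached as high, and 19 of the 24 were highest in IEL replicate 2. Carry-over of epithelial RNA or cells in varying amounts would give this pattern, and purification of the cells, as the labels name it, would reduce it. Genes regulated together within the IELs could also exceed random sets of unrelated genes. The correlation therefore cannot tell carry-over from transcription by the IELs themselves, which was not tested. Among abundant enterocyte genes, named here after their values were seen, Fabp2 and Fabp1 rose by 3.94 and 3.23 but were highest in IEL replicate 1 (Fabp2 8.26, 7.42 and 6.52, Fabp1 8.38, 7.98 and 6.45 in replicates 1, 2 and 3), while Apoa1 and Apoa4 lay at 0.08 and 0.49 and did not pass, so the listed genes did not move alike.

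Car2 was 9.11, 9.14 and 9.10 on the IEL arrays, where it exceeded Naive-like cells by 6.01 ± 0.19. Its value in IEL replicate 2 lay 0.042 ± 0.29 (SE) above the mean of the other IEL arrays, against a range of 0.09 to 1.89 between the 5th and 95th percentiles of the called epithelial genes. The difference lies outside this range by less than its error, a margin that was set after the value was seen. That error takes in the spread of other genes, and the SD of Car2 itself over the IEL arrays was 0.02. Carry-over and expression by the IELs cannot be told apart for this gene on 3 arrays.

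Heat shock and immediate early transcripts were higher in IELs. The mean of the heat shock list medians was 1.07 higher on the IEL arrays than on the lymph node arrays, whose own medians spanned 0.67. Only the intestinal tissue was agitated at 37 °C, so this step may contribute, but handling cannot be told apart from tissue and subset, since no lymph node sample went through it. Epithelial carry-over is open too: IEL replicate 2 held the highest median of the heat shock list (8.28) and of the immediate early (8.48) and epithelial lists (6.93), but the lowest heat shock median lay in replicate 1 and the lowest epithelial one in replicate 3, so 3 arrays do not decide it.

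With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. For IELs against Naive-like cells the real split gave 1152 genes and the highest other split 0; for Type-1 against Naive-like cells 63 and 1; for IELs against Type-1 cells 1140 and 1. In each case 1 split of 10, the real one, gave as many genes. For the F test the real split gave 1200 genes and was the 1 split of 100 drawn to do so. That share lies under 0.05 when arrays are exchanged freely. Each subset holds 1 date-coded array, and these deviated together at correlations of 0.229 to 0.382, which the splits did not take into account; with the date code as a term the number of genes differing among the 3 subsets was 1406. The highest other split gave 1037. Only 3 of the other splits kept the IEL arrays together, and these gave 852 to 1037 genes, while those that parted them gave at most 17. The F test therefore rests mainly on the IELs. So few splits cannot exclude chance for the difference between Naive-like and Type-1 cells.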

How the results depend on the processing

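The fit without the 2 arrays of lowest weight was chosen after seeing the data; the other settings were planned. Of 243 named differences (242 with the filter on dim genes) 0 to 26 were lost in each setting with all or 8 arrays. Without the 2 arrays of lowest weight 15 were lost, and within the arrays without the date code 56. None reversed, but groups without overlap rarely can. Array weights gave 1920 genes for IELs against Naive-like cells and 1884 genes differing among the 3 subsets (F test). All rows without collapsing gave 35 genes for Type-1 against Naive-like cells and classes of 13 (exclusive to Type-1 cells), 4 (exclusive to Naive-like cells), 15 (shared by IELs and Type-1 cells) and 2 (shared by IELs and Naive-like cells); more rows were tested there. Within the 6 arrays without the date code, where fewer arrays were fitted, the pairwise counts were 534, 20 and 565, the F test 527, and the markers exclusive to or shared by subsets 392. Of these, markers exclusive to IELs numbered 268, to Type-1 cells 9 and to Naive-like cells 2; markers shared by Naive-like and Type-1 cells 107, by IELs and Type-1 cells 7 and by IELs and Naive-like cells 2.

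The replicate number as a block gave 1378, 81 and 1405 genes and 8 shared by IELs and Naive-like cells, and changed no call of a list, while 3 named differences were lost; of 81 list tests the filter on dim genes lost 5 calls and added 4, quantile normalization again lost 4 and added 3, genes of 1 list only lost 6 and added 1, the fit without the 2 arrays of lowest weight lost 6 and added 2, and the description sets lost 1, the immediate early list. The arrays without the date code lost 4: ribosomal proteins (IELs against Naive-like), sterol synthesis and chemokine receptors (Type-1 against Naive-like) and NK receptors (IELs against Type-1). With 1 array left out 0 to 3 were lost, 0 to 4 added, and the immediate early list changed sign once, uncalled (below). It, sterol synthesis, NK receptors and oxidative phosphorylation were lost in more than 1 setting. By title number, the deviations of same-numbered arrays correlated at -0.015 to 0.382, over 0.1 in 6 of 9 pairs. The descriptions form 3 other sets, by running numbers and date code. Arrays of the same set correlated at 0.073 to 0.382 (mean 0.181), over 0.1 in 6 of 9 pairs. These include all 3 date-coded pairs (0.229 to 0.382). Arrays of different sets correlated at -0.29 to 0.123 (mean -0.09), over 0.1 in 1 of 18 pairs. Since deviations were taken from subset means, a positive mean for the one kind of pair pulls the other down. The main fit did not match arrays by set. These sets as a block gave 1397, 82 and 1452, 19 exclusive to Naive-like cells and 9 shared by IELs and Naive-like cells. Without the 2 arrays of lowest weight there were 110 genes for Type-1 against Naive-like cells, 20 exclusive to Naive-like cells, 36 shared by IELs and Naive-like cells, and a correlation of 0.157 between the fold changes of IELs and Type-1 cells over Naive-like cells. The cause was not tested.

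With 1 array left out, counts ranged from 826 to 1227 (IELs against Naive-like), 34 to 87 (Type-1 against Naive-like), 724 to 1308 (IELs against Type-1) and 771 to 1392 (genes differing among the 3 subsets). The markers exclusive to IELs ranged from 390 to 654, to Type-1 cells from 14 to 23 and to Naive-like cells from 2 to 19. The markers shared by IELs and Type-1 cells ranged from 13 to 26, markers shared by Naive-like and Type-1 cells from 148 to 188, those shared by IELs and Naive-like cells from 3 to 24, and all markers exclusive to or shared by subsets from 584 to 860. The correlation of the fold changes of IELs and Type-1 cells over Naive-like cells ranged from 0.230 to 0.363. An estimated correlation kept 19 of 51 list calls: 9, 4 and 6. The immediate early list, lower in Type-1 cells at adjusted p = 0.029, had a median of 0.02 without Type-1 replicate 2 (adjusted p = 0.92) and from -0.28 to 0.02 with any 1 array left out, with adjusted p from 7.9e-05 to 0.92. Quantile normalization again gave 774 higher and 505 lower calls for IELs against Naive-like cells (792 and 360 without it) and 783 and 464 for IELs against Type-1 cells (827 and 313 without it). Without detection calls, how many dim genes lie at background is unknown.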

Other observations

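None of 46 oxidative phosphorylation genes and none of 59 ribosomal protein genes passed the limma test in IELs against Naive-like cells, with medians of 0.18 and -0.21; the camera calls were lost with an estimated correlation, at adjusted p = 0.67 and 0.53. Of 18 glycolysis genes 2 rose, Tpi1 (1.57 ± 0.23, SE) and Pfkp (1.41 ± 0.33). Of 34 cell cycle genes 12 rose and none fell (16 adjusted over the list alone), with Mki67 at 2.56 ± 0.36 and Top2a at 1.60 ± 0.25, and an adjusted p = 0.11 with an estimated correlation; epithelial genes moved in the same arrays. Of 28 genes of fatty acid handling 6 rose, led by the epithelial genes Fabp2 and Fabp1, with Acadl at 1.48 ± 0.25 (adjusted p = 0.15 with an estimated correlation). Of 17 genes of the aryl hydrocarbon receptor and TGF-β response 5 rose and 1 fell, among them Tiparp (2.76 ± 0.25) and Ahr (2.08 ± 0.30), at adjusted p = 0.29 with an estimated correlation.

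Adhesion and receptor genes split in IELs against Naive-like cells. Of 31 chemokine receptor and adhesion genes 7 rose and 7 fell, Itgax by 4.86 ± 0.29 upward and Ccr7 at -2.94 ± 0.29, with a median of -0.04 and a mean of 0.06, and camera gave an adjusted p of 0.60. Of 27 cytokine receptor genes 5 rose and 6 fell, with a median of 0.12 and a mean of -0.16 (adjusted p = 0.41). Of 27 type 17 genes 2 rose and 4 fell, Cd163l1 by -2.37 ± 0.32 among them, at adjusted p = 0.0069, and 0.059 with an estimated correlation. In IELs against Type-1 cells 2 rose and 4 fell (2 and 9 adjusted over the list alone), Cd163l1 at -2.09 ± 0.32 and Serpinb1a at 1.27 ± 0.21 among them, at adjusted p = 0.0021, and 0.043 with an estimated correlation, but 0.066 over the genes that stand in no other list. Of 13 type 2 genes 2 rose and 1 fell, with Hpgds at 2.50 ± 0.22, a median of -0.13 and a mean of 0.11, at adjusted p = 0.95. Trgv5 and Trgv6, at 1.12 ± 0.39 and 0.24 ± 0.36, did not pass.

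Cd8b1 lay at 10.35 ± 0.15 (SD, n = 3) in Naive-like cells, 8.21 ± 0.20 in Type-1 cells and 7.54 ± 1.30 in IELs, where single arrays read 8.88, 7.46 and 6.27. Cd8a was higher in IELs, at 9.61 ± 0.33 against 6.21 ± 0.78 in Naive-like and 6.00 ± 0.89 in Type-1 cells. The difference in Cd8b1 between the lymph node subsets, -2.14 ± 0.47, did not pass (limma adjusted p = 0.14). Of 9 measured markers of αβ T cells 1 rose and 4 fell in IELs against Naive-like cells, Trat1 by 1.49 ± 0.22 upward and Cd28 by -1.90 ± 0.26 (adjusted p = 0.16 with an estimated correlation). Of 18 B-cell and plasma cell genes only Ighm passed, at -1.25 ± 0.21; H2-Ab1 varied by 1.76 (SD) within Naive-like cells and by 1.23 within Type-1 cells. Of 21 myeloid genes 1 rose and 1 fell, and of 17 erythroid, platelet, stromal and mast cell genes only Pecam1 passed, at -2.81 ± 0.30. Of 13 NK and innate lymphoid markers 8 rose and 1 fell in IELs against Naive-like cells, Kit by 3.87 ± 0.52 and Osbpl3 by 4.17 ± 0.30.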
